A study of Mus musculus with 2 samples.

How the data were processed

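Chromatin from C2C12 myoblasts infected with a Flag-Msx1 retrovirus or the empty vector was immunoprecipitated with an anti-Flag antibody and sequenced on the Solexa platform. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 minutes, chromatin was sheared to about 500 bp, and libraries went through 18 PCR cycles and a gel cut of 150 to 300 bp, for inserts of 50 to 200 nt. There were 2 GEO samples and 4 lists of reads, 3 for Flag-Msx1 and 1 for the vector. Run names in the labels place experiment 1 on the flow cell of the vector and experiments 2 and 3 on another.

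The deposited files hold signed positions of single reads by chromosome, in categories U0 and U1, and no count per feature, so every count used here was summed from these deposited positions. The build was mm8, per the submitters' processing notes, and the aligner was not given in the sources used here. The series design states that enriched regions were found with a Poissonian background model and then compared with the vector; those regions were not used here.

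Experiments 2 and 3 listed most reads 2 times, at the same position on the plus strand and 1 bp apart on the minus strand. Of the minus-strand positions, 38.5% and 36.9% had a neighbour at 1 bp in experiments 2 and 3, against 0.803% in experiment 1 and 0.289% in the vector, and 65.6% and 62.3% of plus-strand positions were listed an even number of times, against 3.17% and 2.84%. How this arose was not examined. It was undone by merging minus positions 1 bp apart, which was not foreseen in the plan and was decided after the files were examined. The listed reads of experiments 1, 2 and 3 and the vector, 898155, 2253463, 2057033 and 1813909, became 898155, 1313402, 1221761 and 1813909. Keeping 1 read per position and strand in each run removed a further 3.33%, 18.8%, 17.1% and 2.93%, and 868204, 1067081, 1012447 and 1760728 reads remained. The analyses used autosomes and X. Experiments 2 and 3 shared 1.48% of the exact plus-strand positions of the smaller list, 1 and 2 shared 1.13% and 1 and 3 shared 1.10%. These were 4.84, 3.57 and 3.62 times the sharing at offsets of 5 to 24 bp, against 3.06, 2.03 and 1.89 times for experiments 1, 2 and 3 with the vector, and the excess was not explained.

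Read starts were shifted 60 bp toward the fragment centre and counted in windows of 500 bp at steps of 250 bp. The pooled Flag-Msx1 count was tested with a one-sided Poisson test against the largest of the genome-wide rate (0.59 reads per window over 2496 covered Mb) and the vector rate in the window and the surrounding 1, 5 and 10 kb, scaled by total reads (factor 1.67). Values of p were adjusted by the Benjamini-Hochberg method over 3010556 windows with at least 1 Flag-Msx1 read, and passing windows that touched were merged. Leaving windows without reads out of the adjustment makes it more lenient, and adjusting over all windows of the covered length gave 37515 regions. The named regions are the 25 with the smallest p and the 3 highest and 3 lowest bins of 100 kb that passed, a rule fixed before the data were examined.

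Regions were compared between flow cells by an overlap of at least 1 bp, with 1000 random placements. Chromosome shares were tested with Fisher's exact test, and bins of 100 kb with 20 or more reads with an exact binomial test. Ratios of counts have exact intervals and shares have Wilson intervals, at 95%. Against 0 vector reads the floor was 3 reads. Calculations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9.

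The tests were tested on simulated data drawn from the vector's rates. For the enriched regions, over 4188254 windows, 0 of 50 added regions of 5-fold, 9 of 50 of 10-fold, 38 of 50 of 20-fold and all 50 of 40-fold were recovered, with 1 false call among 98. With so few changed regions the adjusted threshold is stricter than in the data, so these shares do not measure recovery there. For the same reason the 1 false call does not measure the share of false regions in the data. For the bins of 100 kb, over 25051 bins, 169 of 200 bins changed by 2-fold were recovered (84.5%), with 6 false calls among 175.

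Alternatives covered the read filter, shift, window, threshold, scaling, test, depth and each experiment left out. Planned counts of regions near 11 gene lists and of reads over the Msx1 exons were not run, because the gene table at hand belongs to another build (GRCm38), and base composition was not examined for lack of a sequence of mm8.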

Results

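Msx1 is a homeodomain transcription factor known to hold back the differentiation of muscle precursors. Its occupancy was mapped in C2C12 cells, a mouse myoblast line that can be driven to form myotubes. The cells carried a retrovirus that expressed Flag-tagged Msx1 or the empty vector, and chromatin was immunoprecipitated with an antibody against the Flag tag and sequenced (ChIP-seq). Each group was 1 GEO sample. The Flag-Msx1 sample held 3 experiments, each with its own list of read positions, and the vector sample held 1. Experiment 1 shared a flow cell with the vector, and experiments 2 and 3 shared another. After the filters, experiments 1, 2 and 3 held 868042, 1066874 and 1012224 reads on the autosomes and X, or 2947140 together, and the vector held 1759847. With 1 sample per group the tests on reads compare these libraries and not the conditions. Nothing in the labels says that the 3 experiments came from separate cultures, so each experiment is given by its own value. Intervals are 95% intervals and cover counting error only. Coordinates are those of mouse build mm8, on which no gene annotation was used here, so that regions are named by position.

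The comparison of Flag-Msx1 with vector asked where tagged Msx1 sat in the myoblast genome. Flag-Msx1 reads gathered in 41413 short regions, which covered 1.25% of the covered genome and held 24.3% of the reads of experiment 1, 23.5% of experiment 2 and 23.6% of experiment 3, against 2.06% of the vector reads (Wilson interval 2.04 to 2.08%). Being low in the vector was part of the call, and regions called without it held more of the vector reads, 4.06% for experiment 1 and 4.74% for experiments 2 and 3. The region with the smallest p lay on chromosome 1 from 94533751 to 94535250, with 48.4, 45.9 and 41.5 reads per 1000000 kept reads (RPM) in experiments 1, 2 and 3 and 2.27 in the vector. The median region was 750 bp wide, with the 10th and 90th percentiles at 500 and 1000 bp and the widest at 3250 bp. The most enriched window of a region stood at a median of 8.96 times its expected count, with the 10th and 90th percentiles at 5.37 and 17.9. The 41413 regions held 36263 vector reads in all, so these values rest on few vector reads per region and have no interval.

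Each window of 500 bp was tested with a one-sided Poisson test against the largest of the genome-wide rate and the scaled local vector rates, and called at a Benjamini-Hochberg adjusted p under 0.01 over 3010556 windows. For each experiment taken alone, the reads of a whole region were tested only against its genome-wide rate, without the vector and without adjustment. In this one-sided Poisson test 30223 of the 41413 regions (73.0%) had p under 0.05 in all 3 experiments, 10023 in 2 and 1167 in 1. These counts say nothing about the vector and only describe regions that were chosen on the pooled reads of these experiments. The count depended on the test: an exact binomial test of Flag-Msx1 against vector reads in each window, for windows with 8 or more Flag-Msx1 reads, called 13275 regions, and 3015 on all windows with a read, while the Poisson test on windows with 8 or more reads called 39260. Keeping windows by their Flag-Msx1 reads before the binomial test favours windows high in Flag-Msx1, so the adjusted p-values behind the 13275 are lenient. A threshold of 0.0001 called 23983, and counting every listed read called 82005. Experiment 1 alone gave 16627 regions, and 15194 of the 41413 had under 10 reads in their top window.

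**Figure D1:**
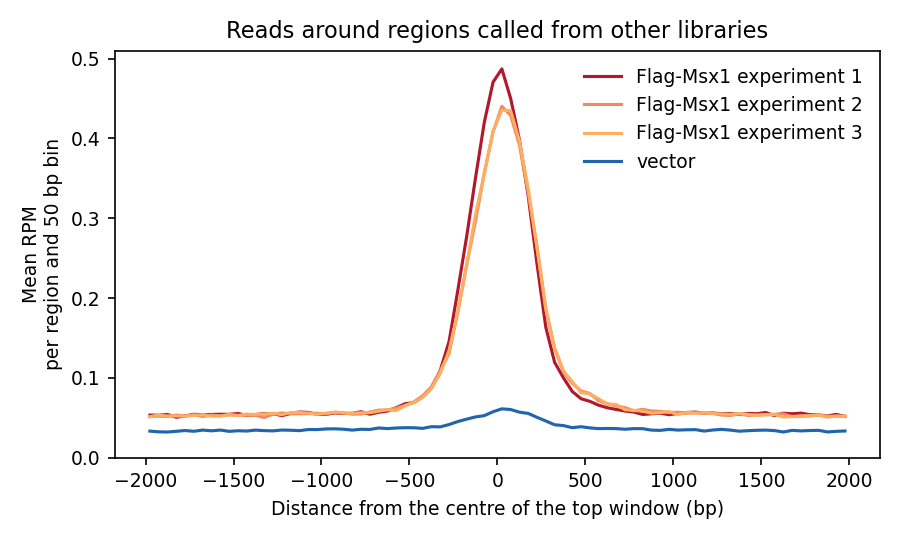
Mean RPM per region and 50 bp bin (y axis) against the distance in bp from the centre of the top window (x axis), with 1 line per library. Experiments 2 and 3 and the vector are drawn around regions called from experiment 1 and experiment 1 around those called from the others, all without the use of the vector. The central 250 bp on each side stood 6.73, 6.32 and 6.39 times above the flanks in experiments 1, 2 and 3, and 1.61 times in the vector.

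Among the 25 regions with the smallest p, every region was higher in each of the 3 experiments than in the vector in RPM. This follows in large part from their choice by the pooled excess over the vector. The largest of the 25 p-values in the Poisson test was 1.2e-88. That test takes the expected rate as known, so its p-values leave out the counting error of the vector, which the intervals of the ratios include. The region at the top of the list on chromosome 1 held 133 Flag-Msx1 reads against 4 vector reads, an RPM ratio of 19.9 (exact interval 7.58 to 73.9). Such ratios rest on scaling by total reads. With the vector scaled by background bins (factor 1.07), the top window of this region stood at 65.4 times its expected count, against 41.8 with total reads. On chromosome 8 the region from 88269001 to 88271750 held 188 reads against 3 (ratio 37.4, interval 12.6 to 183). On chromosome 17 the region from 3156501 to 3157500 held 86 reads against 1 (ratio 51.4, interval 8.97 to 2052). On chromosome 19 from 57256751 to 57258000 there were 114 reads against 3, and on chromosome 14 from 46556001 to 46557000 there were 115 against 4. Another region of chromosome 8, from 82329751 to 82331000, held 94 reads against 1, and on chromosome 5 the stretch from 65156751 to 65158000 held 110 against 2. On chromosome 4 from 149110251 to 149111250 there were 123 reads against 3. On chromosome 3 the region from 57823001 to 57824250 held 78 Flag-Msx1 reads and 0 vector reads, at least 15.5-fold higher against a floor of 3 vector reads.

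Chromosome 15 held 4 of the named regions, from 59613251 to 59614750 (180 reads against 7), from 51539501 to 51541000 (128 against 5), from 83299001 to 83300000 (110 against 7) and from 8753251 to 8754250. The last of these had the most Flag-Msx1 reads of the 25, 209, but also 17 vector reads, and so the lowest ratio, 7.34 (interval 4.48 to 12.8). It was also the only named region that passed the genome-wide test in the vector. On chromosome 3 from 122114001 to 122115750 there were 155 reads against 9, on chromosome 13 from 63709751 to 63710750 there were 91 against 2, and on chromosome 9 from 116224251 to 116225250 there were 96 against 3. Chromosome 1 held further named regions from 155918251 to 155919500 (97 against 1) and from 62818751 to 62819750 (77 against 2), chromosome 2 from 163271501 to 163272250 (92 against 3) and from 60489501 to 60490750 (76 against 1), and chromosome 11 from 20377001 to 20378250 (90 against 2) and from 108884251 to 108886000 (79 against 1). The others were on chromosome 6 from 120983001 to 120984000 (101 against 3), chromosome 17 from 83220001 to 83221750 (137 against 7) and chromosome 10 from 120038751 to 120040000 (142 against 6). The largest difference between experiments in RPM was on chromosome 15 from 51539501 to 51541000, with 31.1, 58.1 and 38.5 RPM.

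**Figure D2:**
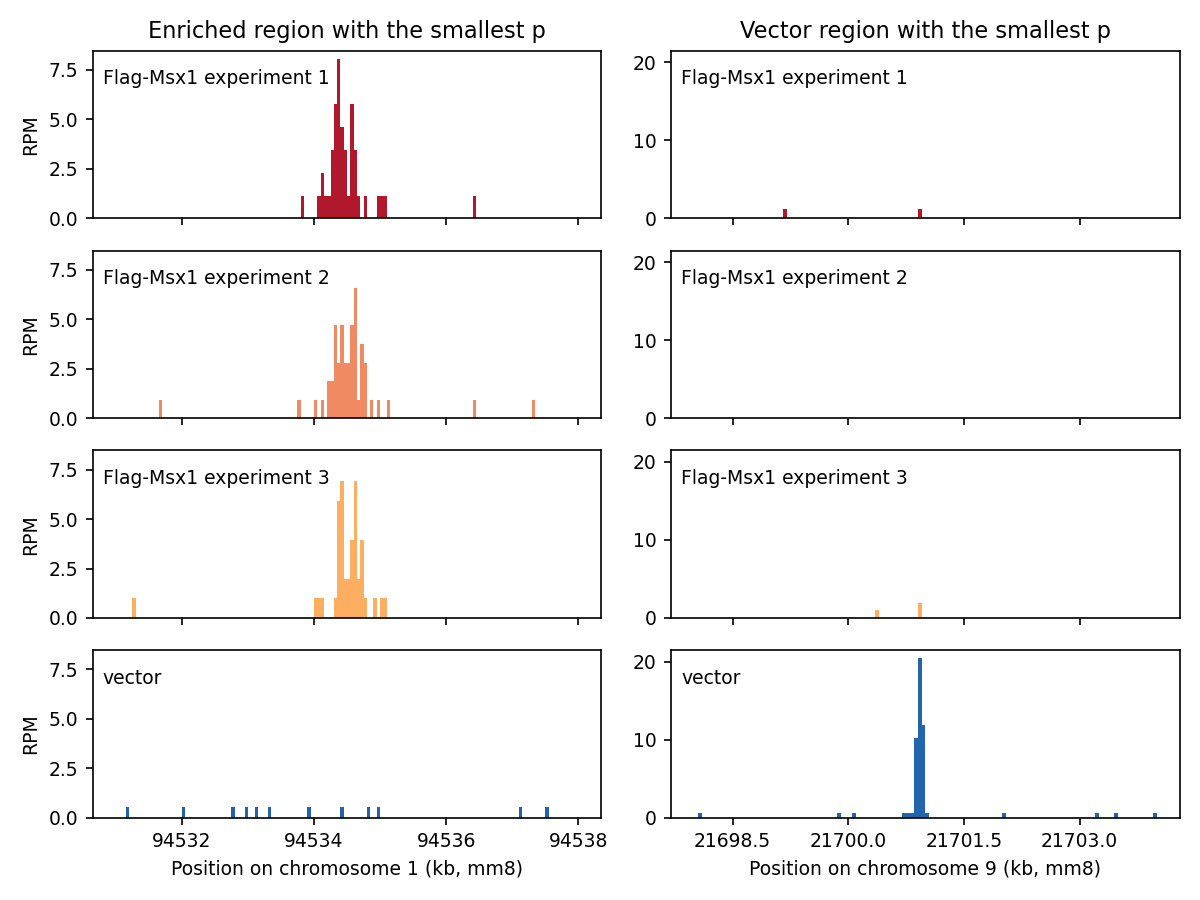
RPM in 50 bp bins (y axes) along the enriched region with the smallest p, on chromosome 1, and the vector region with the smallest p, on chromosome 9 (x axes, position in kb, mm8), with 1 row per library. The chromosome 1 region held 48.4, 45.9 and 41.5 RPM in the 3 experiments and 2.27 in the vector, and the chromosome 9 region held 79 vector reads against 3 from all Flag-Msx1 experiments.

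Exchanging the groups asked how many regions the method calls for the library with no tagged protein to capture. The vector stood above Flag-Msx1 in 61 regions at matched depth, where Flag-Msx1 stood above the vector in 28951. The control in this exchange was the enriched Flag-Msx1 library, so the 61 are not a background rate of the method. Tested only against its own genome-wide rate, the vector gave 1043 regions. Of the 61, the region with the smallest p, on chromosome 9 from 21700501 to 21701250, held 79 vector reads and 3 Flag-Msx1 reads. Others held more of both, such as 398 vector reads and 253 Flag-Msx1 reads on chromosome 5 from 2999751 to 3002500. On chromosome 2 from 32839751 to 32840750 there were 51 vector reads against 2, and on chromosome 11 from 55451001 to 55451750 there were 29 against 1. These 4 were chosen after their values were seen.

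The same test between Flag-Msx1 experiments, at 868042 reads in each library, called between 243 and 279 regions, against 15278 to 15751 for each experiment over the vector and 29 to 32 for the vector over each experiment. Where a Flag-Msx1 experiment was the control, its own enrichment raised the expected counts and so lowered the number of calls. These counts therefore do not compare the size of the difference from the vector with that between experiments.

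Regions from the separate flow cells were compared to ask whether the same places were found again. Of the 16627 regions called from experiment 1, 12587 (75.7%, Wilson interval 75.0 to 76.3%) overlapped a region called from experiments 2 and 3, against a mean of 1.67% and a highest value of 1.97% in 1000 random placements on the same chromosomes. In the other direction 12513 of 33695 regions (37.1%) were found again, against 0.825% by chance. Both calls used the same vector reads. Unchanged groups simulated against these reads gave 10 and 64 regions, of which 7 overlapped. All of these were false calls. With the vector reads split at random between the flow cells the recovery was 68.6%.

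Read counts in 10 kb bins rose and fell together in the 3 experiments. The Pearson r across bins was 0.848 between experiments 1 and 2, 0.845 between 1 and 3 and 0.853 between 2 and 3, and the Spearman rho was 0.641, 0.636 and 0.651. With the vector the r of the experiments lay between 0.514 and 0.523 and the rho between 0.520 and 0.529, so the gap was smaller in rho than in r. Bins are not independent replicates, so these values only describe the libraries. Between experiment 1 and the sum of the other 2 the r was 0.879, and 0.674 once reads within 1 kb of regions were left out.

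The regions were not spread evenly along the chromosomes. The densest 1 Mb bin, on chromosome 10 from 83000001 to 84000000, held 104 regions, against a median of 13 over 2432 bins, and 381 bins held 0. The 5 densest bins also had more vector reads, 981 to 1545 against a median of 680 per bin. It was followed by chromosome 18 from 5000001 to 6000000 with 85 regions, chromosome 13 from 63000001 to 64000000 and chromosome 15 from 58000001 to 59000000 with 82 each, and chromosome 16 from 30000001 to 31000000 with 81. The variance of the count per bin was 16.2 times its mean. Of all regions, 62.3% had the top window of another within 10 kb, against a mean of 29.5% and a highest value of 30.5% in 1000 random placements.

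Chromosome X stood apart with 569 regions, or 3.84 per covered Mb, while the autosomes held 17.4 per Mb, from 13.2 on chromosome 14 to 22.9 on chromosome 11. Its share of reads was also lower in Flag-Msx1, at 2.79% against 3.39% in the vector, a ratio of 0.824. Chromosome 13 had the highest ratio, with 5.33% of Flag-Msx1 reads against 4.60% of vector reads (ratio 1.16), followed by chromosome 3 (1.09) and chromosome 10 (1.07). Chromosome 5 (0.901), chromosome 8 (0.911) and chromosome 7 (0.930) had lower shares in Flag-Msx1.

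In two-sided Fisher exact tests adjusted by the Benjamini-Hochberg method over 20 chromosomes, 18 shares differed between the pooled Flag-Msx1 and the vector libraries, 10 higher and 8 lower in Flag-Msx1. In these exact tests chromosome 6 (adjusted p = 0.847) and chromosome 12 (adjusted p = 0.0514) did not pass. The vector lay outside the range of the 3 experiments for 18 chromosomes, and between pairs of experiments 1 chromosome differed at most. Any 1 of 4 libraries is often the lowest or the highest by chance, and the shares sum to a fixed total. The count of chromosomes with the vector outside the range is thus only a description. Without the reads within 1 kb of regions the ratio of chromosome X was 0.987 and that of chromosome 13 was 1.11. In the Fisher tests 18 shares still differed without those reads. Chromosome X still passed (adjusted p = 0.0185 in the Fisher test), and chromosome 6 now passed (adjusted p = 0.0032 in the Fisher test).

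**Figure D3:**
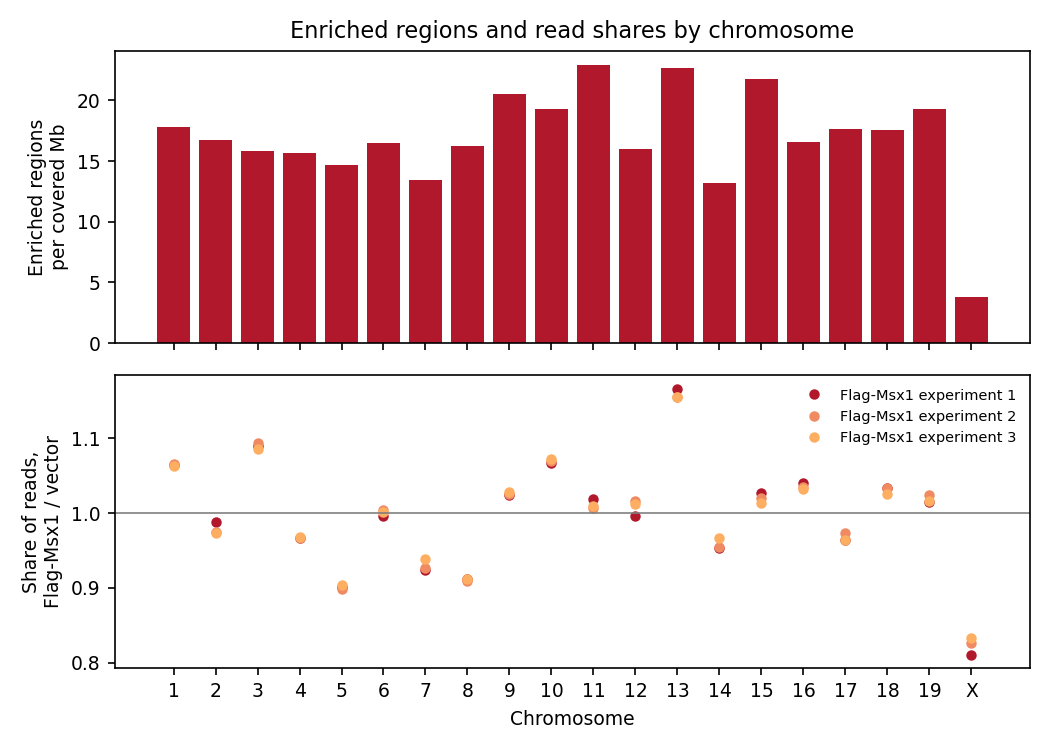
Enriched regions per covered Mb (upper y axis, bars) and the share of reads in each Flag-Msx1 experiment divided by the share in the vector (lower y axis, points) by chromosome (x axis). Chromosome X has 3.84 regions per Mb against 17.4 on the autosomes, and its points lie lowest, while those of chromosome 13 lie highest.

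Broad stretches of the genome also differed in read count between Flag-Msx1 and vector. Scaled by total reads, 4125 of 25009 bins of 100 kb were higher in Flag-Msx1 and 7219 lower. The highest bin was on chromosome 4 from 3300001 to 3400000, with 119 Flag-Msx1 reads against 13 vector reads, a log2 ratio of 2.36 (interval 1.62 to 3.40). On chromosome X from 119200001 to 119300000 the log2 ratio was 2.13 from 21 reads against 2 (interval 0.62 to 5.79), and on chromosome 5 from 22900001 to 23000000 it was 2.10 from 552 against 76 in a bin with 15 regions. Without the reads near regions, and scaled by the totals of the remaining reads, the log2 ratios of these bins on chromosomes 4, X and 5 were 1.99, 2.54 and 1.15. The new totals by themselves moved the ratios up. The bin on chromosome X held 0 regions, and the lowest bin, on chromosome 7 and also with 0 regions, moved from -2.66 to -2.25. The lowest bins were on chromosome 7 from 136200001 to 136300000, at -2.66 with 22 reads against 86 (interval -3.46 to -2.02), on chromosome 5 from 29200001 to 29300000, at -2.63 with 28 against 106, and on chromosome 4 from 146100001 to 146200000, at -2.58 with 6 against 24. The last of these did not pass in experiment 1 alone (log2 ratio -1.30, adjusted p = 0.11 in the exact binomial test). With experiment 1, 2 or 3 left out its log2 ratio was -3.30, -2.42 and -1.97.

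The test was a two-sided exact binomial test per bin with 20 or more reads, called at a Benjamini-Hochberg adjusted p under 0.05. The split between higher and lower bins depended on the scaling: 36.4% of the called bins were higher with total reads, 48.6% (2584 higher, 2731 lower) without the reads near regions, and 88.1% (9968 higher, 1351 lower) with the vector scaled by background bins, which moved the median log2 ratio from -0.28 to 0.36. The same test called at most 1 bin between 2 experiments. Higher bins held a median of 6 regions and lower bins a median of 0. Across bins the log2 ratio and the number of regions had a Pearson r of 0.69 and a Spearman rho of 0.71. This association was in part built in, because regions were called on the same excess and their reads count in the bins. Among bins without a region, 379 were called higher and 2062 lower with total reads. Scaled by their own totals, with reads near regions left out, 756 were higher and 823 lower.

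**Figure D4:**
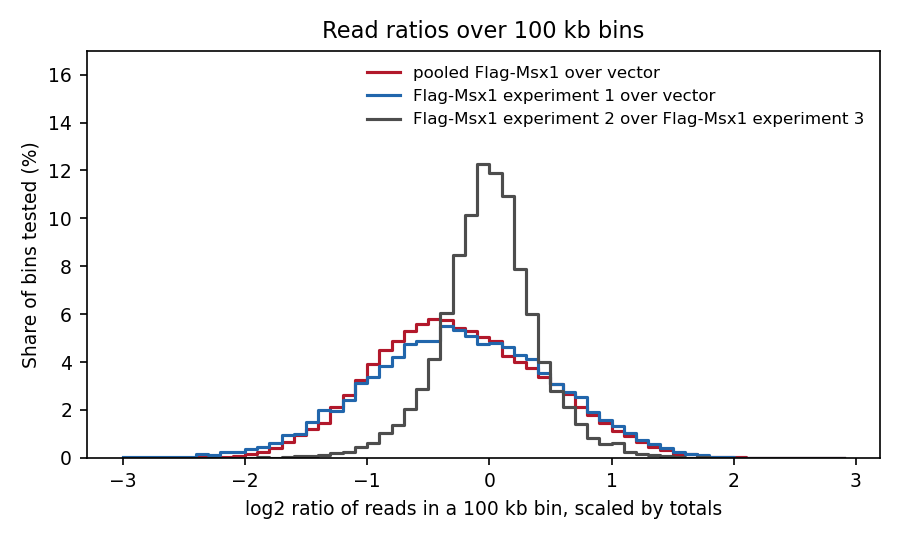
Share of tested 100 kb bins in percent (y axis) by the log2 ratio of reads scaled by totals (x axis), for the pooled Flag-Msx1 reads over the vector, for experiment 1 over the vector on the same flow cell, and for experiment 2 over experiment 3. The ratios over the vector spread more widely than those between experiments, which differed in at most 1 bin.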

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

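The tests on the regions in which the vector stood above Flag-Msx1, the broad bins and chromosome X in this part were all chosen after the patterns had been seen. The read categories were not tested further.

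Reads of the category U1 were kept with the others, and the categories were not compared in the report. They made up 0.00475% of the listed reads of Flag-Msx1 experiment 2 (107 reads) and 0.00554% of experiment 3 (114 reads), above the vector at 0.000662% (12 reads, Wilson interval 0.000378 to 0.00116%). Experiment 1 had 0.00122% (11 reads).

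Of the 61 regions in which the vector stood above Flag-Msx1, 47 had Flag-Msx1 at no more than 10-fold the genome-wide rate, and in these the vector stood at 32.7-fold and Flag-Msx1 at 1.38-fold; a limit of 3-fold, which gave 41 regions, was used at first and raised to 10 after the vector region with the smallest p, on chromosome 9, was seen to fall outside it. Of the listed vector reads there, 91.5% lay at distinct positions (93.5% with the 3-fold limit) against 97.1% genome-wide. This share cannot decide on repeated amplification of a few fragments. The regions were called on 1 read per position and strand, so a pile of a few positions could hardly be called. Plus-strand reads lay a median of 92 bp upstream of minus-strand reads (quartiles 72 and 116 bp, upstream in 42 of 42 regions with enough reads). The 1000 Flag-Msx1 regions with the smallest p had a median of 124.5 bp. The reads in the vector regions were picked after the shift of 60 bp, which by itself sets plus reads upstream of minus reads. The distance therefore cannot tell immunoprecipitated fragments around a point from other sources of reads. Foreign DNA in both libraries of the flow cell cannot be told apart from its absence: per kept read, experiment 1 stood at 1.23 times experiments 2 and 3 (18 reads against 35, exact interval 0.657 to 2.23), and Flag-Msx1 reads there are few because the regions were chosen for that. Material of another immunoprecipitation in the vector library and sites occupied only in vector cells also stay open, and no biological explanation was tested.

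Broad differences between Flag-Msx1 and vector were found also away from the regions. Called regions alone do not account for them: among 13244 bins of 100 kb that held no region, 1579 (11.9%; 756 higher, 823 lower) were called with reads near regions left out and the bins scaled by their own totals. In the same bins, a difference between flow cells as the whole explanation is argued against by the 368 bins called between experiment 1 and the vector on the same flow cell, and the spread between experiments by the at most 1 bin called between 2 of them, at fewer reads. Binding too weak to be called as regions, and a difference between the libraries in base composition or chromatin yield, stay open. With 1 vector library, a trait of that library and an effect of Msx1 cannot be separated by the design.

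Chromosome X held 4.54 times fewer regions per Mb than the autosomes. Vector reads were 0.555 times as dense on chromosome X. Autosomes thinned to that density held 11.2 regions per Mb, against 4.72 on chromosome X (700 regions) when it too was called against its own read rate, a ratio of 2.36, or 1.73 for the autosome with the fewest. With a fixed p of 1e-05 in place of the adjusted threshold the ratios were 2.31 and 1.68. Lower density, including that from a lower copy number, is thus argued against as the whole explanation, although it takes up part of the gap, and chromatin state and base composition of chromosome X stay open and were not tested.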

How the results depend on the processing

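Alternatives chosen after the data were examined were those on the double listing, the adjustment over all windows, reads outside regions, split vector reads, swapped calls with all reads (63 against 61), minimum reads per window, background scaling of the bins and the 3-fold limit. The count of regions, 41413, lay between 28951 and 59537 under the alternatives that kept it within 1.5 times, and between 31565 and 33695 with an experiment left out. It was 82005 with all listed reads, which leaves in both the double listing and repeated positions, and 50584 with the listing undone and repeated positions kept. It was 23983 at a threshold of 0.0001, 13275 with the exact binomial test on windows with 8 or more reads, 3015 with it on all windows with reads, and 16627 with experiment 1 alone, which has fewer reads. Keeping 1 bp pairs gave 53980. The 25 named regions were called again in 500 of 500 alternatives, but 24 remained when regions that pass in the vector were left out. They were chosen for the smallest p and the alternatives reuse the same reads, so being called again was nearly fixed in advance. The named bins passed in 37 of 38; the bin on chromosome X had too few reads to test with an experiment left out or experiment 1 alone. The r of 0.879 between flow cells was 0.693 in 1 kb bins and 0.674 outside regions. Recovery between flow cells was 75.5% with overlap of at least 50% of the shorter region and 83.1% at the stricter threshold. Bins of 500 kb gave 1276 higher and 2292 lower of 5101, from fewer bins; reads outside regions gave 2584 and 2731; background scaling gave 9968 and 1351, so that the balance of higher and lower bins rests on the scaling. Experiment 1 alone gave 4221 lower bins, and leaving out an experiment gave 3835 to 3897 higher and 6230 to 6420 lower. The cause was not tested for the other shifts. The tests of gene lists and of the Msx1 exons were not run. No paired analysis was possible because each group is 1 sample. Depth limits weak regions: 15194 had under 10 reads in their top window.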

Other observations

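The test of gene density in this part was chosen after the region counts had been seen.

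No relation between regions per Mb and gene density was detected across chromosomes. Protein-coding genes per covered Mb, counted in the GRCm38 gene table by chromosome, and regions per Mb had a Pearson r of 0.20 (permutation p = 0.38, adjusted p = 0.75) and a Spearman rho of 0.17 (permutation p = 0.46, adjusted p = 0.75) over 20 chromosomes, and an r of 0.27 without the 2 chromosomes farthest from the median gene density. Over the 19 autosomes the r was 0.078 (permutation p = 0.75) and the rho 0.098 (permutation p = 0.69), also with an adjusted p of 0.75 over the 4 tests. Chromosome 11 had 22.9 regions and 13.6 genes per Mb, while chromosome 13 had 22.7 regions and 7.27 genes. The builds of the counts differ, and 20 chromosomes cannot exclude a weak relation.

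The vector had more reads of its own where regions were found. In regions called on the flow cell of experiment 1 without the use of the vector, the vector stood at 2.65 times an even spread, against 14.1 and 14.2 times for experiments 2 and 3. In regions called on the other flow cell it stood at 2.62 times, against 14.6 for experiment 1.

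Mitochondrial positions made up 0.0540% of the listed vector reads (Wilson interval 0.0507 to 0.0575%), against 0.0189%, 0.0197% and 0.0231% in experiments 1, 2 and 3.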
